A study of Mus musculus with 7 samples.

How the data were processed

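Replication origins were mapped by sequencing of short nascent strands, the short DNA pieces that form where a replication fork has just started. Per the labels' protocols, denatured DNA was separated by size on a sucrose gradient, the fractions named F4 and F5 were digested with λ-exonuclease, which spares strands that begin with an RNA primer, and the remaining single strands were made double-stranded before library preparation. The cells were mouse embryonic stem cells (mESCs). The 7 samples form 3 conditions with 2 libraries each and 1 Input sample. WT libraries came from untreated cells, APH libraries from cells given 0.5 µM aphidicolin, an inhibitor of replicative DNA polymerases, for 2.5 h, and CDC6 libraries from cells given 1 µg/ml doxycycline for 30 h to overexpress CDC6, a protein that loads the replicative helicase at origins. WT replicate 1 came from another mESC line and was described as submitted earlier. The other 5 libraries came from mESCs that carry the doxycycline-inducible transgene. The labels do not state that the 2 libraries of a condition came from separate cultures, so p-values measure only the spread between these samples, which may be technical. DNA libraries do not measure CDC6 levels, so the induction was not checked. No processed list of the Input sample was used here.

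Each condition had 1 deposited list of origins, and each of the 6 libraries had 2 deposited lists. Per the submitters' processing notes, FastQC, BWA 0.7.10, SAMtools 0.1.19, Picard 1.107, MACS2 2.0.10 and bedtools 2.23.0 were used, with GRCm38, mm10 and mm9 named as builds. Their roles and settings are not given in the sources used here. The ends of the chromosomes in the lists fit mm10, which is GRCm38. The first list of a library, called MACS peaks below, has the layout of MACS2 and holds for each peak the authors' score, fold ratio over a control, and −log10 p-value and q-value. All 6 libraries were set against the same control, and the deposited lists end at a q-value of 0.1 with widths of at least 400 bp. The second deposited list of a library holds regions with 2 scores per region, of which the second is at least 1.5 times the first. The meaning of these scores is not given in the sources used here. The deposited condition lists carry the same 2 scores, and how the authors combined libraries is not stated. Peak scores and ratios are the authors' and were used in the main comparisons only to rank or describe peaks within a list. Across lists, scores of the second lists were correlated with MACS folds to check labels, and their first score, relative to the median of its list, was compared between libraries by chromosome.

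The file labels of the second lists went against those of the MACS lists. Each row of the WT condition list was a row of the second list labelled APH 1, each row of the APH condition list a row of the second list labelled CDC6 1, and each row of the CDC6 condition list a row of the second list labelled CDC6 2. The MACS peaks of the 2 libraries of the named condition overlapped at least 99.4% of each condition list. The condition lists and the MACS peaks were therefore used as labelled in every main comparison, and the second lists, as labelled, only in alternatives. No group was changed from the values. Of the WT, APH and CDC6 condition lists, 99.4%, 99.98% and 99.95% met both MACS lists of the condition and 2 second lists. Of the rows that met all 4 lists, 20062 of 20729, 31648 of 32904 and 31369 of 32258 were in the condition list. A region can therefore lack a WT origin although both WT libraries have a MACS peak there.

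The files give no read numbers, so the sequencing depth behind each list is unknown, and the number of peaks limits the precision. Autosomes and X were used. Overlap meant at least 1 bp. Random expectation came from 100 placements of a list within the span of the same chromosomes with widths kept (10 placements for MACS peaks). The 3 condition lists were merged into regions and classified by the lists that held them. Peak strength was the percentile rank, by −log10 q-value, of the strongest MACS peak of a region within its library. Gene positions came from a RefSeq table of GRCm38.p6, which gives start and end without strand. The start-site windows fixed before the data were examined were therefore replaced by windows of 1 kb on each side of both ends of 21631 protein-coding genes, called gene ends. No genome sequence was used here, so the planned comparison of GC content, CpG islands and G-quadruplex motifs was not run. Intervals for differences in shares are 95% intervals from 1000 resamplings of chromosomes. They cover the spread between chromosomes, not between libraries, because each condition has 1 list.

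The number of MACS peaks (by midpoint) was counted in 1 Mb bins and in bodies of protein-coding genes of at least 50 kb, scaled to the mean total, and tested as log2(number + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with all 3 conditions in 1 fit, features with a mean of at least 5 peaks and Benjamini-Hochberg adjusted p under 0.05. Such folds understate the change where numbers are low. In data simulated for the APH against WT comparison, with Poisson spread only, the fit recovered 80% of bins changed 2-fold and 98% changed 4-fold among 2546 bins, with 14 false calls. Among 1604 simulated genes it recovered 12% of those changed 2-fold and 62% of those changed 4-fold, with 3 false calls. Unchanged features had the same mean in every simulated library, whereas the real WT libraries correlated across bins with r = 0.491. The simulated recovery therefore does not carry over to the real comparisons. Overlap functions were tested on simulated regions against a base-by-base count, with 0 mismatches in 20 sets. The 10 fixed gene lists were compared by exact McNemar tests over genes, adjusted over 20 tests, and by camera with a preset correlation of 0.01 and with an estimated one. Camera needed at least 5 measured genes, which only the long-gene list and the zinc finger list had. McNemar tests are over the genes of 1 pair of lists, and neighbouring genes can share an origin. Other comparisons used exact permutation tests over the 6 libraries, two-sided unless stated. Groups of 2 against 2 allow no p under 0.05. Other steps ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

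Named genes followed a rule fixed before the data were examined: the 5 genes per class with the highest mean percentile at a gene end, leaving out predicted genes; the 5 rises and 5 falls per contrast to WT with the smallest p where none passed; and the first members of each fixed list within each outcome. Not every gene that met the rule is named. Alternatives covered rebuilt and equal-length lists, overlap and window sizes, stricter peaks, pseudocounts, filters, bin sizes, normalization, the replicate number as a block, and leaving out each replicate. Those chosen after seeing the data were rebuilding from MACS peaks alone without 1 library, replacing the WT list by the peaks of 1 WT library, leaving out chromosomes 8 and X, and the 20000 strongest peaks of each library.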

Results

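Replication origins were mapped by short nascent strand sequencing in mouse embryonic stem cells (mESCs) without treatment (WT), under mild replication stress from aphidicolin, an inhibitor of replicative DNA polymerases (APH), and with overexpression of the licensing factor CDC6 (CDC6). Each condition had 2 libraries and 1 list of origins. WT replicate 1 came from another mESC line than the other 5 libraries. The read depth of the libraries is unknown. MACS2 peaks numbered 94747 in WT 1, 81056 in WT 2, 74540 in APH 1, 71435 in APH 2, 72384 in CDC6 1 and 82071 in CDC6 2, and these numbers limit the precision of what follows. Positions are on mm10.

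The number of origins was compared to ask how many sites are used with and without stress. The APH list held 31653 origins and the CDC6 list 31384, against 20178 in the WT list, which is 1.57 and 1.56 times as many. The origins had a median width of 720 bp in WT, 670 bp in APH and 737 bp in CDC6, and covered 18.0 Mb, 26.5 Mb and 27.5 Mb. The X chromosome held 2.01% of WT, 3.42% of APH and 2.80% of CDC6 origins. There is 1 list per condition, so these numbers have no replicate error. In single libraries, X held 3.30% of the MACS peaks of WT 2, 4.15% and 3.55% in APH, and 2.24% and 2.73% in CDC6. WT 2 thus lay above both CDC6 libraries. The X share of WT 1 was 0.548 times the mean of the other libraries. Whether the low X share of the WT list goes with the condition or with WT 1 was not tested. For the number of sites, the single libraries did not show the same order as the lists. The mean number of MACS peaks was 87902 ± 9681 (SD, n = 2) in WT, 72988 ± 2196 (SD, n = 2) in APH and 77228 ± 6850 (SD, n = 2) in CDC6. The mean of the 4 stressed libraries minus that of WT was -12794 peaks (exact two-sided permutation p = 0.133 over 15 splits, adjusted p = 0.333 over 5 measures, smallest possible p = 0.0667), with -5948.5 without WT 1 and -19639.5 without WT 2. With the second lists as labelled, of which 4 labels went against the MACS lists (those of WT 2, both APH libraries and CDC6 1), the APH to WT ratio was 1.01, and lists rebuilt from MACS peaks without WT 1 or without WT 2 gave 0.706 and 0.604 for APH and 0.673 and 0.576 for CDC6, where a single WT library stands against sites found in both stressed libraries.

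**Figure D1:**
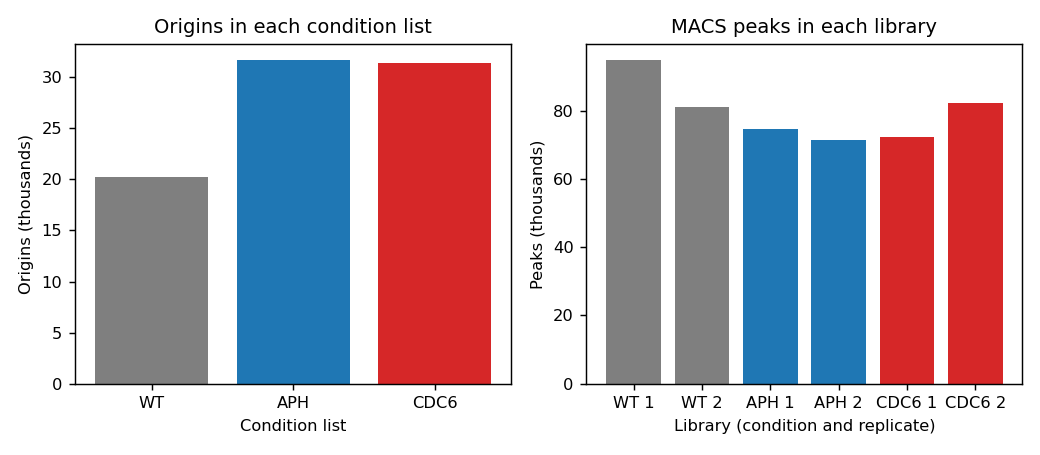
Number of origins in each condition list (left) and of MACS peaks in each library (right), both in units of 1000. The WT list is the shortest with 20178 origins, while WT 1 has the most peaks, 94747.

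Origins of the 3 lists were overlapped to ask which sites are shared between conditions. Of the WT origins, 71.7% overlapped an APH origin and 68.6% a CDC6 origin. In the other direction, 45.4% of APH and 43.8% of CDC6 origins overlapped a WT origin, and 63.7% of APH origins overlapped a CDC6 origin. The mean of random placements was at most 2.22%. Merged, the lists made 46639 regions. All 3 lists held 11888 regions (25.5%), both stress lists but not WT held 8218 (17.6%), APH alone 9017 (19.3%), CDC6 alone 9396 (20.1%) and WT alone 3873 (8.30%). WT and APH shared 2449 further regions, and WT and CDC6 1798. In lists rebuilt from MACS peaks, leaving out WT 1 or WT 2 set all 81056 or 94747 peaks of the other against sites found in both libraries of a stress. This moves the shares by construction. Of APH origins, 77.0% had a WT origin without WT 1 and 64.1% without WT 2. Of WT origins, 57.4% had an APH origin without WT 1 and 39.1% without WT 2. A CDC6 origin was found for 46.1% of WT origins without WT 1 and 41.7% without WT 2. CDC6 origins had a WT origin in 67.2% without WT 1 and in 72.2% without WT 2.

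The 26631 regions without a WT origin were mostly not free of signal in the WT libraries. Of these regions, 84.3% overlapped a MACS peak of at least 1 WT library (13.3% for random placements), 36.1% peaks of both (3.19% for random placements), and 15.7% (4186 regions) neither. Of the regions held by both stress lists alone, 59.0% had a peak in WT 1, 86.0% in WT 2 and 5.90% in neither. Regions held by APH alone had a peak in WT 1 in 47.4% and in WT 2 in 59.3%, and those held by CDC6 alone in 61.6% and 50.4%. With the peaks of 1 WT library in place of the WT list, the regions of both stress lists alone numbered 3402 or fewer and those of all 3 lists at least 16480. The WT side then held 94747 or 81056 peaks in place of 20178 origins. The direction of these changes was thus fixed by construction. All libraries shared 1 control, and its part in the overlap was not tested.

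**Figure D2:**
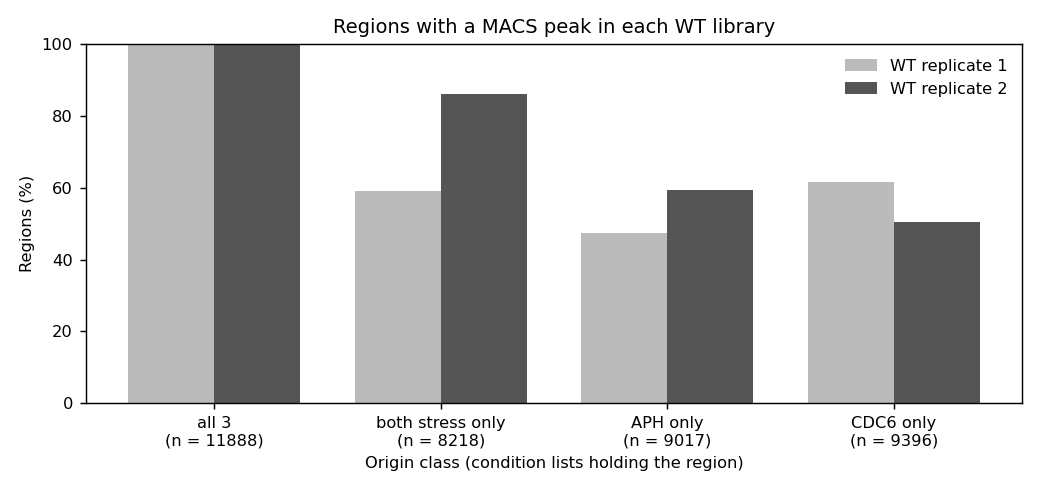
Share of regions (%) that overlap a MACS peak of WT replicate 1 or WT replicate 2, by the condition lists that hold the region. Regions held by both stress lists but not by WT had a peak in WT 1 in 59.0% and in WT 2 in 86.0%.

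The strongest origins at gene ends, within 1 kb of either end of a protein-coding gene, were named for each class. In all 3 lists they lay at Yy1 (chromosome 12, 108791925 to 108795018), which encodes a zinc finger transcription factor, at Ncoa2, a nuclear receptor coactivator, at Rev1, a translesion DNA polymerase, at Dyrk1a, a protein kinase, and at Celf1, an RNA-binding protein. In both stress lists alone they lay at the vomeronasal receptor gene Vmn1r48 (chromosome 6, 90033279 to 90036137), at Tmsb4x on X, at Tmem65, and in 1 region that touches the histone genes H2ac18 and H3c14. The APH list alone held regions at Kdm4a (chromosome 4, 118136793 to 118137377), a histone demethylase gene, at Padi2, at Tmem229b, and at 1 region next to Dmpk and Dmwd. The CDC6 list alone held regions at Arid1a (chromosome 4, 133756705 to 133757498), which encodes a chromatin remodeller subunit, at the growth factor receptor gene Igf1r, at Cd209b and Zfp423 on chromosome 8, and at Hoxd9. The WT list alone held regions at Cux1 (chromosome 5, 136568508 to 136569234), Cacnb3, Prrt1, Mob1b and Rhou, the last on chromosome 8. At Yy1 the fold over the control ran from 9.53 in WT 2 to 14.4 in both APH libraries, with 14.3 in WT 1. At Vmn1r48, although no WT origin was listed, it was 6.97 in WT 1 and 8.03 in WT 2. Cd209b had MACS peaks in the CDC6 libraries alone, 8.29-fold and 5.59-fold over the control. All 5 regions named for WT alone had MACS peaks in every stressed library. The regions at Padi2, Tmem229b, Dmpk and Dmwd, Zfp423 and Hoxd9, named for 1 stress list alone, had MACS peaks in every library. That at Kdm4a had them in every library except CDC6 1. Arid1a stood at 7.63-fold over the control in WT 1, and Igf1r at 6.28-fold in WT 1 and 9.05-fold in APH 2. Arid1a lacked a peak in APH 1, and Igf1r in WT 2 and APH 1. Chromosome 8 held 8.26% of the peaks of WT 1.

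Peak strength was compared to ask whether origins seen in every condition were stronger. Within the same library, peaks of regions held by all 3 lists ranked 12.4 ± 1.67 percentile points (SD, n = 6 libraries) above those of regions held by both stress lists alone, and they ranked higher in 6 of 6 libraries (exact two-sided sign-flip permutation p = 0.03125, the smallest possible). The difference lay between 10.4 and 15.2 points. The classes were defined from the same libraries, so the test is not independent of them. In the WT libraries, a lower rank of regions without a WT origin is favoured by that definition. The means cover only regions with a peak, which for both stress lists alone were 4845 of 8218 in WT 1. Regions of all 3 lists were also wider (median 1168 bp against 775 bp), which favours a higher strongest peak. The direction was thus favoured in advance.

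The share of regions at gene ends was compared to ask where in the genome each class of origin lies. Regions held by all 3 lists lay at a gene end in 45.3%, which is 9.03 times the 5.01% of random placements. Regions of both stress lists alone did so in 9.11% (2.15 times random), of APH alone in 4.70% (1.21 times), of CDC6 alone in 16.8% (4.08 times) and of WT alone in 7.20% (1.81 times). WT and CDC6 shared regions of which 33.9% lay at gene ends, and WT and APH regions of which 8.17% did. Gene bodies held 71.4% of the regions of all 3 lists, 40.3% of those of both stress lists alone, 38.1% of APH alone and 56.0% of CDC6 alone. The difference between all 3 lists and both stress lists alone was 36.2 points (95% interval 34.7 to 37.5), that between CDC6 alone and APH alone 12.1 points (95% interval 11.2 to 13.2), and that between both stress lists alone and WT alone 1.91 points (95% interval 0.414 to 3.60). The classes were not matched for peak strength. Regions of all 3 lists held stronger peaks than those of both stress lists alone, and stronger origins lay more often at gene ends in each list. Whether the first difference goes beyond this was not tested. With the peaks of 1 WT library in place of the WT list, the first difference was 20.9 points without WT 1 and 37.3 points without WT 2. The second was 10.8 points without WT 1 and 2.03 points without WT 2. The WT side was then longer and less strict than the WT list, which by construction moves regions between classes. Of the 20000 strongest peaks of each library, 41.3% in WT 1 and 26.5% in WT 2 lay at gene ends, against 29.2% and 34.3% in APH and 39.7% and 35.8% in CDC6, so that the WT libraries spanned the range of the others.

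**Figure D3:**
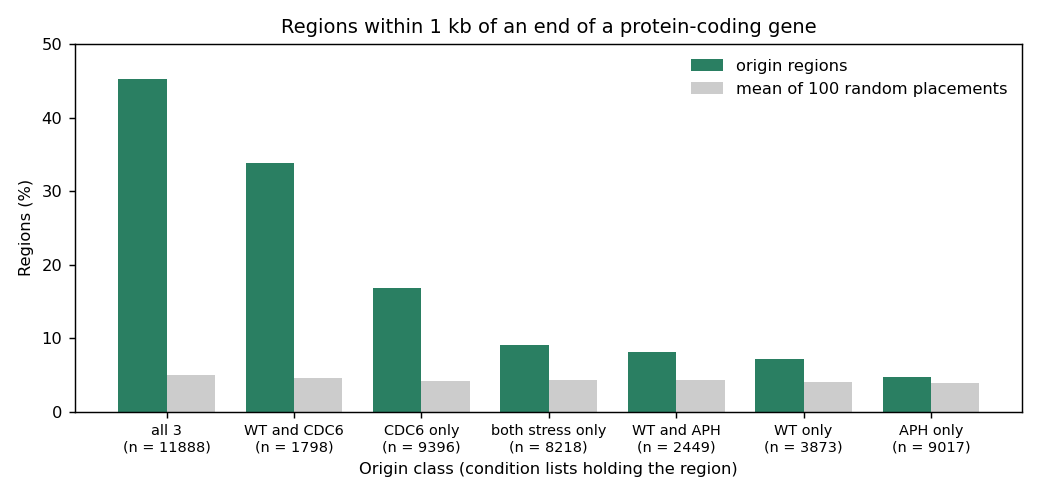
Share of regions (%) within 1 kb of an end of a protein-coding gene, by the condition lists that hold the region, beside the mean of 100 random placements. Regions held by all 3 lists reach 45.3% and those of the APH list alone 4.70%.

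The distance between neighbouring origins was compared to ask whether origins cluster under stress. The median distance was 72.1 kb in WT, 50.8 kb in APH and 47.6 kb in CDC6, against 84.7 kb, 55.2 kb and 55.2 kb for random placements of as many origins. A neighbour within 10 kb was found for 18.6% of WT origins (random 15.2%), 23.4% of APH origins (random 22.2%) and 26.9% of CDC6 origins (random 22.2%). These shares were 1.23, 1.05 and 1.21 times random, and each was above the highest of 100 placements (16.1%, 23.0% and 23.1%). Among the MACS peaks of single libraries, the share was 0.954 times random in WT 2 and 0.900 times in APH 1, both below random, and 1.02 to 1.05 times in the other 4 libraries. With equal numbers of origins drawn from each list, the APH share of 15.5% was no longer above the highest placement (15.9%). The difference between the lists in this ratio was not tested. Random placements were independent of each other, so they could overlap, and they were not limited to sequence in which peaks can be called. How far this moves the ratios was not tested, so these ratios alone do not show whether origins cluster.

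Library overlap was compared to ask whether libraries of the same condition resemble each other. The covered bases of the APH libraries had a Jaccard index (shared over total covered bases) of 0.569 and those of the CDC6 libraries 0.486, whereas that of the WT libraries was 0.205. Between conditions the index ran from 0.200 for WT 1 with APH 1 to 0.400 for WT 2 with APH 1. The mean was 0.420 within and 0.307 between conditions, a difference of 0.113 (exact one-sided permutation p = 0.0667 over 15 pairings, the smallest possible). It was 0.0281 without APH 1, 0.0520 without APH 2, 0.0703 without CDC6 2, 0.204 without WT 1 and 0.234 without WT 2. With the second lists as labelled, of which 4 labels went against the MACS lists, the difference was -0.0150.

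**Figure D4:**
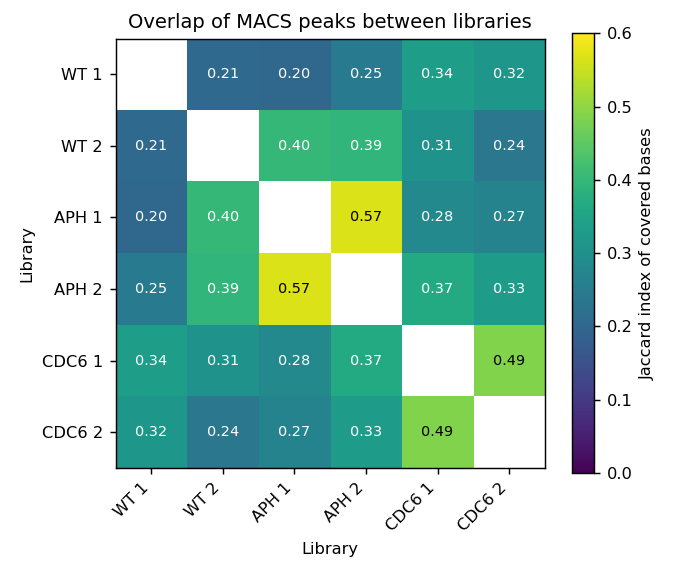
Jaccard index of the bases covered by MACS peaks for each pair of libraries, from 0 (no shared bases) to 1 (the same bases). The APH pair (0.569) and the CDC6 pair (0.486) are the highest, and the WT pair has 0.205.

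Peak density was compared along the chromosomes and in long genes to ask where peaks became denser or sparser. Among 1 Mb bins, limma called 0 of 2545 in APH minus WT, CDC6 minus WT and APH minus CDC6, with 54, 48 and 80 at an unadjusted p under 0.05. Among genes of at least 50 kb, limma called 0 of 1619 in each, with 60, 74 and 90 at an unadjusted p under 0.05. Without any change, a share of about 0.05 of the features would have such a p. The bins lay below that share in each comparison. The genes lay below it in both comparisons with WT and slightly above it in APH minus CDC6. The difference between the WT libraries enters the spread that all groups share, so 0 calls do not show that no bin or gene changed. Without WT 1, limma called 43 bins and 90 genes in APH minus WT and 773 bins and 357 genes in CDC6 minus WT, and without WT 2 it called 994 bins and 276 genes, and 292 bins and 51 genes. The remaining WT library is then assumed to vary like the other groups. APH minus CDC6, in which no library was removed from either group, gave 254 bins and 111 genes without WT 1 and 300 bins and 115 genes without WT 2.

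The genes with the smallest p in these comparisons did not pass the threshold and are given as values. In APH minus WT, the log2 differences on the positive side were 0.91 ± 0.286 (SE, 2 libraries per group) at Erg, an ETS transcription factor gene on chromosome 16, 1.49 at Mid1 on X, 0.78 at Caln1, 1.05 at Sdhaf3 and 0.82 at Lmx1a, a homeobox gene. On the negative side they were -1.17 at Ehbp1, -1.38 at Rapgef6, -1.01 at Zfp385b, -1.28 at Fancc, a gene of the Fanconi anaemia DNA repair pathway, and -1.15 at Pdss2. All had a limma adjusted p of 0.971. In CDC6 minus WT, the values were 1.31 at Zfpm1, a cofactor of GATA factors, 1.16 at Mbp, which encodes a myelin protein, 0.95 at Elfn1, 0.94 at Gse1, -1.24 at Eml6, -1.31 at Csgalnact1, -1.22 at the calcium release channel gene Ryr3, -1.02 at Npas3 and -0.95 at Prim2, a subunit of DNA primase. These had a limma adjusted p of 0.803. Zfpm1, Gse1 and Csgalnact1 lie on chromosome 8, which held 8.26% of the peaks of WT 1 and 4.86% to 5.53% of those of the other libraries. With the second lists as labelled, Erg had -0.14, Lmx1a -0.19 and Zfp385b 0.17 in APH minus WT.

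The 10 gene lists fixed before the data were examined were compared by the number of genes with an origin at a gene end. Of 46 developmental regulators, 24 had a WT origin and 37 a CDC6 origin, with 13 gained and 0 lost (exact McNemar adjusted p = 0.00244). Hoxa5, Hoxa13, Hoxd1 and Hoxd13 had origins in all 3 lists, and Hoxa2, Hoxb4 and Hoxc8 in the CDC6 list but not in WT. Of 63 canonical histone genes, 12 had a WT and 29 a CDC6 origin, with 17 gained and 0 lost (exact McNemar adjusted p = 0.000305); these 17 genes rest on 11 CDC6 origins on 2 chromosomes. H1f2 and H1f3 had origins in all 3 lists, H1f4 and H2ac18 in both stress lists, and H2ac10 and H2ac13 in the CDC6 list. Of 83 ribosomal protein genes, 19 had a WT and 29 a CDC6 origin, with 11 gained and 1 lost (exact McNemar adjusted p = 0.0423), among them Rpl14 and Rpl18. Of all 21631 protein-coding genes, 2246 gained and 421 lost an origin at a gene end from WT to CDC6, and 1133 gained and 887 lost one from WT to APH. Among genes without a WT origin, 59.1% of the developmental regulators, 33.3% of the histone genes and 17.2% of the ribosomal protein genes gained a CDC6 origin, against 15.2%, 15.2% and 15.3% of the other genes (Fisher's exact adjusted p = 2.09e-05, 0.00506 and 0.900, a test chosen after the counts were seen). With lists of equal length these shares were 36.4%, 17.6% and 15.6%, against 10.7% of the other genes (Fisher's exact adjusted p = 0.00924, 0.450 and 0.539). All 13 gained developmental regulators had a MACS peak in WT 1 and 6 had one in WT 2. Of the gained histone genes, all 17 had a peak in WT 1 and 10 in WT 2. Of the gained ribosomal protein genes, all 11 had one in WT 1 and 9 in WT 2. Counting all MACS peaks, histone genes with a peak numbered 59 in WT 1 and 37 in WT 2. They numbered 25 and 34 in the APH libraries and 55 and 57 in the CDC6 libraries. Among the 20000 strongest peaks of each library, 31 developmental regulators had a peak at a gene end in WT 1, 20 in WT 2, 22 and 34 in the APH libraries and 33 and 32 in the CDC6 libraries. The lists of equal length are the condition lists cut to their strongest origins, which left the WT list whole. With them, none of the 3 gene lists passed (exact McNemar adjusted p = 0.0712 for developmental regulators, 0.0712 for histones and 0.154 for ribosomal proteins).

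No list passed for APH, where 23 developmental regulators, 15 histone genes and 17 ribosomal protein genes had an origin, and the other 7 lists passed for neither stress within 1 kb of gene ends. Within 5 kb, olfactory receptor genes passed for APH, with 71 in WT and 101 in APH (56 gained, 26 lost, exact McNemar adjusted p = 0.0122), where 1855 of all protein-coding genes gained and 1083 lost an origin. Of 39 licensing and firing genes, 15 had a WT, 11 an APH and 20 a CDC6 origin, with Orc2, Mcm3, Mcm6 and Cdc7 in all 3 lists, Gmnn, which encodes the licensing inhibitor geminin, and Mcm5 in CDC6 but not WT, and Orc1 and Orc4 in none. Of 31 pluripotency genes, 14 had a WT, 13 an APH and 16 a CDC6 origin, with Klf2, Klf4 and Tfcp2l1 in all 3, Fgf4 in both stress lists, Sox2 in CDC6 but not WT, and Nanog and Esrrb in none. Of 38 replication stress response genes, 18 had a WT, 15 an APH and 20 a CDC6 origin, with the checkpoint kinase gene Atr, Timeless and Tipin in all 3 and Chek1 and Clspn in none. Of 35 long genes and fragile site orthologues, 12 had a WT, 12 an APH and 18 a CDC6 origin (exact McNemar adjusted p = 0.156 for CDC6), with Macrod2 in all 3 and Fhit and Wwox in CDC6 but not WT. Housekeeping genes with an origin numbered 12 in WT, 11 in APH and 15 in CDC6 of 28, with Ppia in all 3 and Actb in none. Zfp genes numbered 102, 96 and 107 of 367, with Zfp143 in all 3, and olfactory receptor genes 17, 13 and 16 of 1106, with Olfr212 in all 3. By peak density, the long genes had a median log2 difference of 0.08 in APH minus WT, with 21 of 35 above 0 (camera adjusted p = 0.242 with a preset correlation and adjusted p = 0.731 with an estimated correlation), and of -0.03 in CDC6 minus WT (camera adjusted p = 0.549 with a preset correlation). The 10 measured genes of the zinc finger list did not pass in either contrast. Adjusted over the list alone, limma called 0 genes of both lists, and over all genes tested also 0, where 60 and 74 of all 1619 genes had an unadjusted p under 0.05.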

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

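The tests of explanations, the comparison of the CDC6 list with the APH list over gene lists, the use of 1 WT library in place of the WT list and the 20000 strongest peaks were chosen only after the results were seen, while the difference in gene-end share and the number of peaks per library came from comparisons planned before.

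The CDC6 and APH lists differed in the genes with an origin at a gene end. Of the developmental regulators, 14 had an origin in the CDC6 list and not in the APH list and 0 the reverse (exact McNemar adjusted p = 0.000610), and of the canonical histone genes 14 and 0 (exact McNemar adjusted p = 0.000610). Licensing and firing genes gave 9 and 0 (exact McNemar adjusted p = 0.0130), and ribosomal protein genes 15 and 3 (exact McNemar adjusted p = 0.0188). Of all 21631 protein-coding genes, 2098 had an origin at a gene end in the CDC6 list and not in the APH list and 519 the reverse. Among genes without an APH origin, 60.9% of the developmental regulators had a CDC6 origin, against 14.5% of the other genes (Fisher's exact adjusted p = 2.04e-06), 29.2% of the histone genes (0.0291), 32.1% of the licensing and firing genes (0.0291) and 22.7% of the ribosomal protein genes (0.110, not passing), each against 14.5%. With lists of equal length, this test against the other genes passed for developmental regulators (Fisher's exact adjusted p = 0.000109) and not for licensing and firing genes (0.0553), ribosomal protein genes (0.0553) or histone genes (12.5% against 12.3%). With the same lists of equal length, the exact McNemar adjusted p was 0.00259 for developmental regulators and 0.0260 for licensing and firing genes. It was 0.00259 for ribosomal protein genes and 0.0625 for histone genes. The share of regions at gene ends was 12.1 points higher for the CDC6 list alone than for the APH list alone. It was 2.03 points higher with the peaks of WT 1, and 10.8 with those of WT 2, in place of the shorter WT list. Among the 20000 strongest peaks of each library, licensing and firing genes with a peak numbered 22 in WT 1, 7 in WT 2, 8 and 10 in the APH libraries, and 16 and 15 in the CDC6 libraries. Developmental regulators numbered 22 and 34 in the APH and 33 and 32 in the CDC6 libraries, so APH 2 was highest of these. Histone genes numbered 14 and 17 in APH and 23 and 17 in CDC6. Ribosomal protein genes numbered 14 and 20 in APH and 33 and 26 in CDC6.

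Of the 6 second lists, 4 matched the MACS list of another sample better than that of their own. Across peaks, which are not independent replicates, the score of the list labelled WT 2 had its highest rank correlation with the MACS fold of APH 1 (0.754 against 0.500 with its own), APH 1 with WT 2 (0.693 against 0.503), APH 2 with CDC6 1 (0.837 against 0.631) and CDC6 1 with APH 2 (0.838 against 0.704). Resemblance between libraries of the same condition is argued against, since all 4 best matches lay in another condition. Exchanged file labels are a candidate explanation: by rank correlation the 4 matches form 2 exchanged pairs, and the lists labelled WT 2 and CDC6 1 each overlapped 100% of the APH condition list, the list labelled APH 1 100% of the WT list and the list labelled APH 2 100% of the CDC6 list, against at most 79.6% of any other condition list. By the Jaccard index of covered bases, the list labelled WT 2 was nearest to APH 2 (0.242, against 0.222 with APH 1 and 0.198 with its own), that labelled CDC6 1 was nearly as close to its own MACS list as to APH 2 (0.234 against 0.235), and no biological explanation was tested.

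The WT list was shorter than both stress lists. A larger number of weak peaks in the WT libraries is argued against as the whole cause, since with the 20000 strongest peaks of each library the WT pair still shared 9208 regions, below the 10153 to 15880 of the other 14 pairs. Low overlap of the WT libraries with each other is a candidate explanation: at equal peak number the WT pair shared 32361 regions, and the other 14 pairs 34054 to 56254. Whether unstressed cells use fewer sites cannot be told apart from this, because the stressed libraries held -12794 peaks relative to WT (-5948.5 without WT 1, -19639.5 without WT 2) but the ranges overlapped, with 81056 peaks in WT 2 and 82071 in CDC6 2. WT 1 differs from the other libraries in its cell line and earlier submission, which the design does not separate.

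In the second list labelled WT 1, whose first score is constant along stretches of a chromosome, chromosome 8 stood at 1.56 times the median of the list. That level was 1.53 times the mean of the other libraries for chromosome 8 and 0.485 times for X. An artefact at a single place on chromosome 8 is argued against, since 90.5% of its 1 Mb bins held more MACS peaks in WT 1 than in the other libraries on average, with a ratio of 1.43 to 1.68 in the parts of the chromosome. Another copy number of chromosome 8 and of X in the line of WT 1 is a candidate explanation that these values are consistent with. It was tested only on the data in which it was found, and no other biological explanation was tested.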

How the results depend on the processing

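Rebuilding from MACS peaks without each replicate, replacing the WT list by the peaks of 1 WT library, leaving out chromosomes 8 and X, and using the 20000 strongest peaks were chosen only after the data were seen. Of the values that answer a comparison, 133 kept their direction and side of the threshold or stayed within a set limit, 67 moved beyond it, 12 no longer passed and 5 reversed. Most of the 133 were counts of 0 limma calls that stayed at 0 while both WT libraries were in the fit. They say little about how stable the other results are. The limit was a 95% interval over the origins of 1 list for ratios and shares, and a set ratio for counts. It holds no spread between libraries. Those no longer passing include the strength differences without 1 library, where the smallest possible exact permutation p is 0.0625. Those reversed came from leaving out a WT library or from the second lists as labelled. Values of single named genes kept their sign without passing the threshold in 224 cases, kept it and passed in 25, and reversed in 3. Their size was not compared: Caln1 went from 0.78 to 0.14 in APH minus WT with the second lists as labelled. The cause was not tested except where stated. The labels of 4 of the 6 second lists went against the MACS lists, which limits every value from the second lists as labelled.

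The APH to WT ratio of origin numbers was 1.41 from MACS peaks in both libraries, 1.01 from the second lists as labelled, 1.28 from all 4 lists and 1.74 at equal MACS list length. The CDC6 to WT ratio was 1.34, 1.17 and 1.44 in the first 3 of these. With lists of equal length, 58.7% of WT origins were in APH, 55.5% in CDC6, and 58.3% of APH and 55.1% of CDC6 origins were in WT. Regions held by WT alone numbered 2473 with the upper 50% of peaks. Spacing in APH over random was 1.04 with equal numbers drawn, no longer above all placements. Within minus between conditions, the Jaccard index of the second lists as labelled was -0.0150. Without a filter, limma called 12 genes in APH minus WT, 10 in CDC6 minus WT and 2 in APH minus CDC6. With the second lists as labelled, Erg had -0.14, Lmx1a -0.19 and Zfp385b 0.17 in APH minus WT. With lists of equal length, 0 gene lists passed against WT by exact McNemar test, where gains minus losses were 8 for developmental regulators, 8 for ribosomal proteins and 9 for histones. Within 5 kb of gene ends they were 6 for developmental regulators (exact McNemar adjusted p = 0.125) and 9 for ribosomal proteins (adjusted p = 0.112). The 2 lists that passed within 5 kb were histones for CDC6 (26 gained, 0 lost, adjusted p = 5.96e-07) and olfactory receptors for APH (56 gained, 26 lost, adjusted p = 0.0122).

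Leaving out each replicate gave APH to WT ratios of 0.604 to 1.83 and CDC6 to WT ratios of 0.576 to 2.02. Ratios under 1 came from leaving out a WT library. The highest ratios, 1.76 and 1.83 for APH and 1.78 and 2.02 for CDC6, came from leaving out a library of that stress. Both by construction compare a single library with sites shared by 2. Leaving out a library of the other stress left the ratios from MACS peaks in both libraries, 1.41 and 1.34, unchanged. Both ends of each range of shares that follows also come from comparing a single library with shared sites. The shares ran from 39.1% to 77.9% for WT in APH, 41.7% to 80.5% for WT in CDC6, 43.4% to 77.0% for APH in WT and 38.8% to 72.2% for CDC6 in WT. With 1 WT library, whose peaks outnumber the WT list, regions numbered 16480 to 18710 in all 3 lists and 1150 to 3402 in both stress lists alone. APH alone held 3674 to 4777 and CDC6 alone 3617 to 4656. The difference in Jaccard index ran from 0.0281 to 0.234, and that in peaks per library from -19639.5 to -5948.5. The difference in strength ran from 11.8 to 12.8 points, with an exact permutation p of 0.0625, the smallest that 5 libraries allow. Bins called by limma ran from 0 to 994 in APH minus WT, 0 to 773 in CDC6 minus WT and 0 to 300 in APH minus CDC6, and genes from 0 to 276, 0 to 357 and 0 to 115. The counts above 0 came from leaving out a WT library, which takes the difference of the WT libraries out of the spread. The planned sequence alternatives and rebuilding from both kinds of list without each replicate were not run. The number of peaks limits what low-density genes can show.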

Other observations

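The tests of gains within gene lists, and the ranking of origins by strength, were chosen only after the results were seen.

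Zfp genes and olfactory receptor genes took few of the origins gained at gene ends. Of the 265 Zfp genes without a WT origin, 7.55% gained a CDC6 origin, against 15.5% of the other genes (Fisher's exact adjusted p = 0.000960), and with lists of equal length 5.28% against 10.8% (adjusted p = 0.0125). Zfp219, Zfp282 and Zfp324 were among the 20 that gained one. Of the 1089 olfactory receptor genes without a WT origin, 0.826% gained one, against 16.5% of the other genes, but these genes lie in clusters and are not independent of each other. Olfr1186 and Olfr1509 were among the 9. Of the 22 developmental regulators without a WT origin, 36.4% gained a CDC6 origin with lists of equal length, against 10.7% of the other genes (Fisher's exact adjusted p = 0.00924), among them Gata2, a blood transcription factor gene, Sox9, a cartilage and testis transcription factor gene, and Tbx5, a heart and limb transcription factor gene.

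Origins at gene ends were more frequent among stronger origins in each list. From the weakest 20% to the strongest 20% of origins, the share at gene ends went from 5.65% to 69.6% in WT, from 5.23% to 51.3% in APH and from 6.90% to 57.1% in CDC6. Across 1 Mb bins, which are not independent of each other, the number of peaks correlated with r = 0.909 between the APH libraries, 0.920 between the CDC6 libraries and 0.491 between the WT libraries. WT 1 had its highest correlation with CDC6 1 (0.868) and WT 2 with APH 1 (0.791).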
